A study of Mus musculus with 13 samples.

How the data were processed

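The series holds RNA-seq and ATAC-seq of sorted mouse cells. The deposited RNA-seq table holds raw counts of fragments per gene, made by the authors with featureCounts 2.0.1 over the exons of an mm10 annotation with Ensembl gene IDs, per the file headers. Per the same headers, read pairs were counted as fragments and no strand option was set, so reads were counted without regard to strand, and no option to count reads mapping to several places was set. Trimming with Trimmomatic and alignment with HISAT2 are named without versions per the submitters' processing notes, which also name edgeR. Per the labels' protocols, RNA of sorted cells was amplified with the Ovation RNA-Seq System V2 and sequenced as paired 100-bp reads on an Illumina HiSeq. The labels call each pool of 8 to 10 hearts a biological replicate. They do not say whether PC and RACM of 1 number came from the same pool. The file headers record that the p0 alignment files first carried no number.

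The table has 55487 gene IDs, of which 55141 matched a symbol, and 33066 had any count. Genes passing filterByExpr by cell type (minimum count 10, minimum total count 15) were tested, 18015 in all. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values were computed from the counts and TMM-scaled library sizes. Differences are PC minus RACM. The common biological coefficient of variation was 0.399. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1, so none is given. Intervals on ratios of counts are exact binomial at 95% and, like the floor of 3 counts, cover counting error only, since amplified reads are not independent molecules.

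The 30 gene lists were fixed before the data were examined, as were the main tests, the first set of alternatives and the rule for named genes. Lists with at least 3 measured genes (28) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Camera called 19 lists at the preset correlation and 2 with the estimated one, pacemaker cell identity and neuron markers, the latter with 6 of 16 listed genes measured. The named genes are 16 fixed ones, the 10 largest rises and 10 largest falls among called genes with libraries that do not overlap, at least 10 CPM in the higher cell type and no predicted symbol, per list the 2 genes of smallest p and the first called gene of opposite sign, and for the p number the 6 genes of smallest p with at least 10 CPM. A gene named outside this rule was chosen after its values were seen.

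The p number was tested with an F test of its coefficients in a model with cell type. Whether the numbers pair the libraries was checked. Deviations from the cell type mean correlated across genes by 0.156, 0.234 and 0.237 for p0, p2 and p4, all above 0.1, and each library correlated best with its own number. The numbers were therefore taken to pair the libraries, a pairing that comes from the data and not from a label. These correlations are low, and they do not tell a shared pool from another difference that goes with the number. A fit with the number as a replicate block called 2082 genes. No libraries were near-identical: the chi-square per degree of freedom between replicates was from 26.2 to 65.6.

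Total counts ranged from 14141151 to 22290996. PC libraries had 24643, 23622 and 23013 genes with a count, and RACM libraries 25160, 27073 and 27510. Thinned to 14141151 counts, these became 23091, 22481 and 21776 in PC, and 23997, 25771 and 25726 in RACM. CT010467.1, which lies at the position of Rn18s-rs5, a sequence related to ribosomal RNA and annotated as a pseudogene, took from 9.6% to 13.9% of counts. All 37 genes of the mitochondrial genome had 0 counts in every library, which says nothing of their expression. Without strand, genes with overlapping exons cannot be told apart, which touched 27.5% of genes tested and 335 of the 1309 calls.

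The steps were tested on simulated data, drawn from the real means, library sizes and dispersions for 18015 genes. With 50 genes changed at each size, the edgeR test of PC against RACM recovered 12% at 2-fold, 54% at 4-fold, 70% at 8-fold and 72% at 16-fold, and called 6 unchanged genes. DESeq2 1.42.0 recovered 24%, 66%, 84% and 74% and called 54 unchanged genes. The p number test recovered 65% of 200 genes changed 8-fold in the p4 libraries and called 24 unchanged genes. Alternatives were RLE and upper-quartile scaling, no filter and a filter of 5 CPM in every library of a cell type, the replicate block, each library left out, DESeq2, limma-voom, a 2-fold minimum, and for lists an estimated correlation and fry. The fit with no filter was not run on simulated data, so how many unchanged genes it calls is not known. The ATAC-seq samples were not analysed here. A planned test of exon usage was not run, because the table has 1 row per gene. Some results for single genes and 1 gene list are not reported here.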

Results

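RNA was sequenced from pacemaker cells (PC), which set the heartbeat from the sinoatrial node, and from right atrial cardiomyocytes (RACM), both sorted from neonatal mouse hearts that carried an Hcn4-GFP reporter and a Myh6-mCherry reporter. Each biological replicate pooled tissue from the junction of the node and the right atrium of 8 to 10 hearts. The 6 RNA libraries comprised 3 of each cell type, and the titles number them p0, p2 and p4 in both. The labels of the RNA libraries give the stage as neonatal and do not say what the p number stands for, while p0 is given as the stage of the ATAC-seq samples. Total counts were 19672921, 18371816 and 22290996 for the PC libraries p0, p2 and p4, and 14141151, 15365982 and 19555932 for the RACM libraries in the same order. The 7 ATAC-seq samples of the series, 4 of PC and 3 of RACM, were not analysed here.

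The comparison of PC with RACM asked which genes set pacemaker cells apart from the neighbouring atrial muscle. Genes that define the sinoatrial node were far higher in PC. Isl1, a transcription factor of cardiac progenitors and the sinoatrial node (ENSMUSG00000042258, mm10 chromosome 13 from 116298281 to 116309689, minus strand), reached 65.5 ± 12.1 CPM (SD, n = 3) in PC. In RACM it had 2 counts over all 3 libraries, against 3677 in PC, a ratio of 1680 with a 95% counting interval from 466 to 13900. Tbx3, a repressor of the working myocardial programme (chromosome 5 from 119670669 to 119684724), stood at 319 ± 34.9 CPM in PC and 5.14 ± 1.02 CPM in RACM, a log2 fold change of 5.95 ± 0.22 (SE; edgeR quasi-likelihood test, adjusted p = 6.05e-06). Shox2, another transcription factor of the node, had a log2 fold change of 5.18 ± 0.24 (290 against 8.02 CPM).

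Hcn4, a channel gene of the pacemaker current (chromosome 9 from 58823412 to 58863175), rose from 48.6 ± 15.3 CPM in RACM to 2612 ± 93.4 CPM in PC, a log2 fold change of 5.75. Its reporter was part of the sort, so its direction checks the labels and is no finding. Smoc2, a secreted matrix-associated protein, had a log2 fold change of 5.74, and the T-box gene Tbx18 one of 2.47 (101 against 18.0 CPM, adjusted p = 0.0133). Of the exon bases of Tbx18, 20.6% were shared with another gene, and its call was lost without the PC p0 library (adjusted p = 0.0596). In the list of pacemaker cell identity, 13 of 15 measured genes rose and none fell (14 adjusted over the list alone), and 9 of the 15 also stand in other lists. The list differed from other genes by camera (adjusted p = 3.54e-69), with adjusted p = 0.0053 with an estimated correlation and adjusted p = 0.0947 with an estimated correlation and the replicate block. Hcn4, whose reporter was part of the sort, is among the 13 risers and entered these list tests, which were not run without it. The connexin gene Gjc1 did not pass the edgeR test (log2 fold change 0.37 ± 0.16, adjusted p = 0.238).

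**Figure D1:**
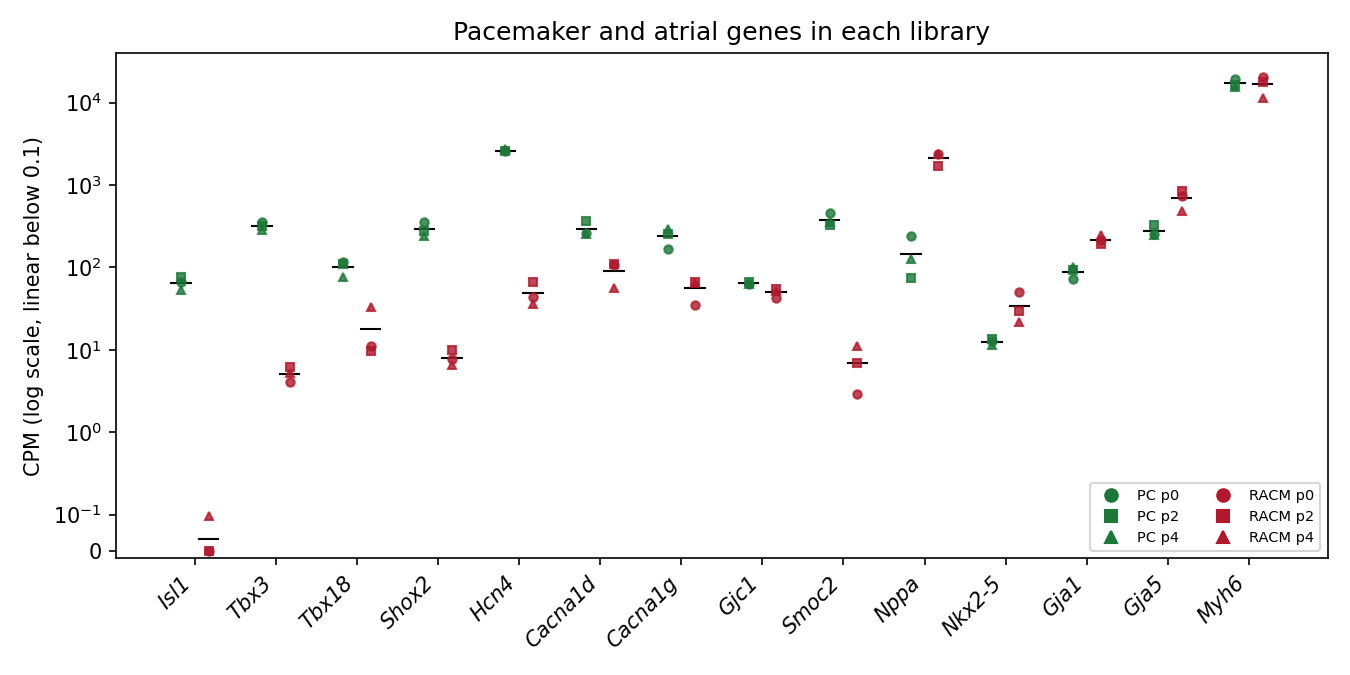
CPM of fixed pacemaker and atrial genes, on an axis that is logarithmic above 0.1 CPM and linear below. Each point is 1 library, with shape giving the p number, green for PC and red for RACM, and black lines mark the means of 3 libraries. Isl1 had 65.5 CPM in PC and 2 counts in all RACM libraries, and Myh6 lay at 17060 and 16600 CPM.

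Several genes of working atrial muscle were lower in PC, though not all. Nppa, which encodes atrial natriuretic peptide (chromosome 4 from 148000722 to 148002079), stood at 147 ± 86.1 CPM in PC and 2155 ± 399 CPM in RACM, a log2 fold change of -3.87 ± 0.42 (edgeR adjusted p = 0.00109). Of its exon bases, 61.5% were shared with the antisense gene Gm13054, where reads counted without strand cannot be assigned. Bmp10, a growth factor of atrial muscle, fell from 1633 to 24.3 CPM (log2 fold change -6.07). The connexin genes Gja1 and Gja5 had log2 fold changes of -1.30 and -1.32, and the cardiac transcription factor Nkx2-5 one of -1.44 (adjusted p = 0.025). The call of Gja5 was lost without PC p0 (adjusted p = 0.0613). That of Nkx2-5 was lost without any 1 of PC p0, PC p2, PC p4, RACM p0 or RACM p2 (adjusted p from 0.0523 to 0.0913). Hamp, the gene of the iron hormone hepcidin, was on the same list and went the other way, at 108 CPM in PC and 4.67 CPM in RACM (log2 fold change 4.53).

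Of the 16 measured genes of the working atrial list, 2 rose and 6 fell (11 adjusted over the list alone), and 11 of them also stand in other lists. The list lay lower by camera (adjusted p = 0.03), a call that was lost with an estimated correlation (adjusted p = 0.42) and without PC p2, PC p4 or RACM p0 (adjusted p = 0.06, 0.0686 and 0.122). Myh6, a myosin heavy chain gene whose promoter drove the other reporter, did not differ detectably (log2 fold change 0.04 ± 0.25, adjusted p = 0.953), and its sign changed with the scaling (-0.02 with upper-quartile scaling). As with Hcn4, its reporter was part of the sort, so its level is no finding on atrial identity.

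Over 18015 genes tested, 665 were higher and 644 lower in PC, 1309 in all at an adjusted p below 0.05, and with the replicate block 2082 genes passed, of which 1267 were among the 1309. Besides Isl1, large rises belonged to Cckar, a receptor of the gut hormone cholecystokinin, with 3400 counts in PC and 2 in RACM (ratio 1560, counting interval from 431 to 12900), and to Th, tyrosine hydroxylase of catecholamine synthesis, at 62.0 ± 8.39 against 0.107 CPM (edgeR adjusted p = 6.05e-06). AI847159 had 1418 counts against 3 (ratio 433, interval from 148 to 2100). Tub followed with a log2 fold change of 7.96, the somatostatin receptor gene Sstr4 with 7.37, AC139348.1 with 6.90, the chitinase gene Chit1 with 6.89 and Syt13 of the synaptotagmin family with 6.81. Among the 10 largest falls, Mmp13, a collagenase, had 3 counts in PC and 630 in RACM (RACM over PC ratio 229, interval from 78.1 to 1110). The others besides Bmp10 were Ms4a7 (-6.61), C1qa (-5.52), Trf (-5.37), Ifi204 (-5.32), Cd163 (-5.24), Lilrb4a (-5.12, with 35.9% of exon bases shared), Tnf (-5.12) and Cd300ld (-5.10), several of which are known from macrophages.

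Libraries of the cell types did not overlap for 1307 of the 1309 genes and for 26.9% of all genes tested, where chance gives 10%. The number of calls depended on single libraries: it was 570 without PC p0, 763 without PC p2, 511 without RACM p2, 727 without RACM p4, and 734 without both p4 libraries, which was chosen after seeing the data. Among the falls, C1qa lost its call without PC p0, PC p2, PC p4, RACM p2 or RACM p4 (adjusted p from 0.0521 to 0.0849), Cd300ld and Ifi204 without PC p0 (0.0653 and 0.0525), and Tnf without RACM p2 (0.0543). By limma-voom C1qa, Cd300ld, Tnf and Cd163 did not pass (adjusted p = 0.239, 0.133, 0.0629 and 0.0945).

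**Figure D2:**
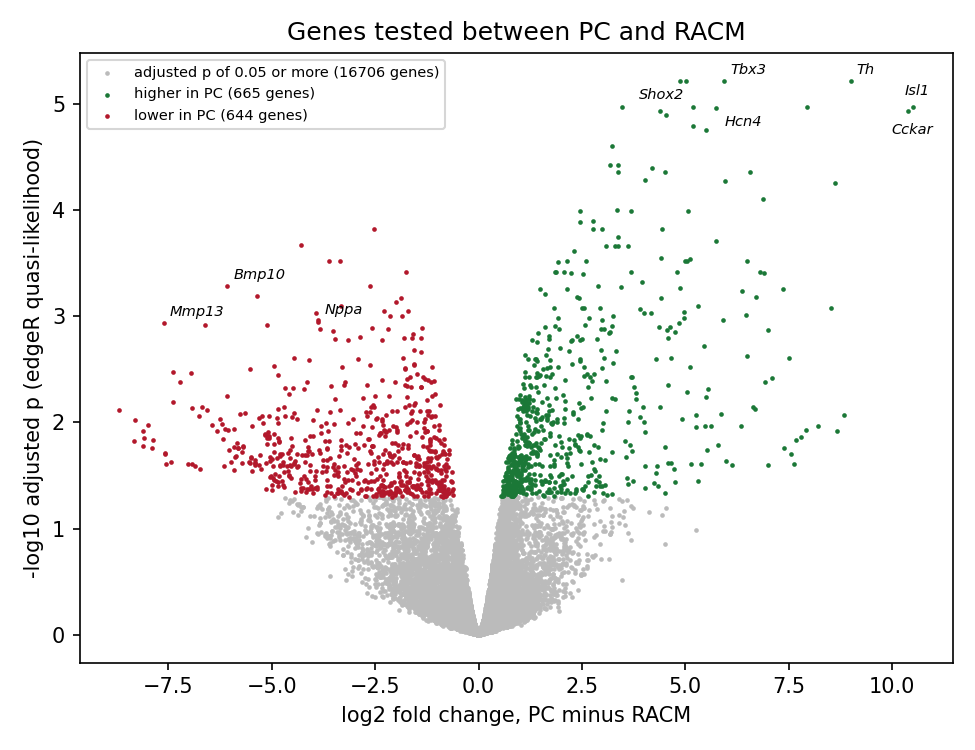
Each point is 1 of the 18015 genes tested, with the log2 fold change of PC minus RACM on the x axis and the negative log10 of the adjusted p on the y axis. Green marks the 665 genes higher in PC and red the 644 lower, and grey the rest.

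Among voltage-gated calcium channel genes, 6 of 11 measured rose and 1 fell (9 adjusted over the list alone), and 3 of the 11 belong to the identity list too. Cacna1g, a T-type channel, had a log2 fold change of 2.10 ± 0.29 (238 against 55.5 CPM), Cacna1d, an L-type channel, 1.69 ± 0.28 (292 against 90.7 CPM) and the subunit gene Cacnb4, with 16% of its exon bases shared with another gene, 2.44. Cacna2d3 fell, with a log2 fold change of -2.22 at 1.43 against 6.72 CPM, a call lost without PC p0, PC p2, RACM p2 or RACM p4 (adjusted p from 0.0534 to 0.125). The list lay higher by camera (adjusted p = 1.78e-05), with adjusted p = 0.277 with an estimated correlation. Among sodium channel genes, 1 of 8 measured fell (5 adjusted over the list alone; 1 rose and 1 fell with the replicate block) and the list did not pass (adjusted p = 0.919 by camera), with a median log2 fold change of 0.77 and a mean of 0.27 where camera's direction was down. The gene that fell, Scn10a, had a log2 fold change of -1.04, a call lost without PC p0 or RACM p2 (adjusted p = 0.0613 and 0.0962). Scn3a, with 3 counts in PC and 71 in RACM, had a RACM over PC ratio of 25.8 (interval from 8.49 to 128) and did not pass (adjusted p = 0.0528), but passed with no filter, by DESeq2 and by limma-voom (adjusted p = 0.0263, 0.00983 and 0.0413).

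Potassium channel genes went both ways, with 3 of 24 measured higher and 5 lower (12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.458). Abcc9, a subunit of ATP-sensitive potassium channels that pericytes also express, fell from 93.0 to 9.21 CPM (log2 fold change -3.33). In RACM p0, p2 and p4 Abcc9 was at 111, 106 and 62.4 CPM, where summed smooth muscle and pericyte markers were at 327, 415 and 746 CPM. The pericyte marker Pdgfrb, looked up after its values were seen, was at 47.4 CPM in RACM and 5.36 CPM in PC, and another, Cspg4, at 15.5 and 37.4 CPM. Whether pericytes account for the fall of Abcc9 was not tested. Of 6 measured connexin genes, 1 rose and 2 fell (3 adjusted over the list alone, camera adjusted p = 0.298). The riser, Gjd3, was at 8.25 against 1.63 CPM, and its call was lost without PC p0, RACM p2 or RACM p4 (adjusted p = 0.0584, 0.0617 and 0.0535).

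Of 20 genes of calcium handling in the sarcoplasmic reticulum, 5 rose and 1 fell (7 adjusted over the list alone). Casq1, a calcium-binding protein of the reticulum, had a log2 fold change of 1.84 ± 0.16 (88.2 against 24.6 CPM) and Camk2a, a calcium-dependent kinase, 1.44. Itpr2 fell (-1.06), a call lost without PC p0, PC p2, RACM p2 or RACM p4 (adjusted p from 0.0597 to 0.0766). The list's camera adjusted p was 0.00247, with adjusted p = 0.364 with an estimated correlation. Of 26 sarcomere genes, 2 rose and 1 fell (9 adjusted over the list alone), and with the replicate block 9 rose and 2 fell. Tpm1, a tropomyosin, stood at 13830 ± 1252 CPM in PC and 6240 ± 336 CPM in RACM, and Tcap at 241 against 103 CPM. Smpx fell (-0.82, adjusted p = 0.0497), a call lost without PC p0, PC p2, RACM p0, RACM p2 or RACM p4 (adjusted p from 0.0856 to 0.156). The sarcomere list's camera adjusted p was 0.00223, with adjusted p = 0.47 with an estimated correlation, and adjusted p = 0.111 by camera without both p4 libraries. In RACM p0, p2 and p4 the summed sarcomere genes were at 126400, 120700 and 90870 CPM and those of calcium handling at 21380, 17900 and 14560 CPM, where summed fibroblast markers were at 1179, 2734 and 7581 CPM and macrophage markers at 220, 575 and 965 CPM. In PC the sarcomere sums were 146400, 148500 and 147400 CPM, and those of calcium handling 23750, 20900 and 19230 CPM.

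Of 45 genes of oxidative phosphorylation, 5 rose and none fell (32 adjusted over the list alone), and with the replicate block 25 rose. Uqcrq of complex III had a log2 fold change of 1.22 ± 0.23 and Sdhd of complex II 0.99 ± 0.21. The call of Uqcrq was lost without RACM p2 (adjusted p = 0.0751), and that of Sdhd without PC p0, PC p4 or RACM p2 (adjusted p = 0.0886, 0.0683 and 0.107). The list's camera adjusted p was 7.38e-13, with adjusted p = 0.42 with an estimated correlation. Fatty acid oxidation had 1 riser among 26 genes (1 adjusted over the list alone), the fatty acid binding protein gene Fabp3 (988 ± 144 against 368 ± 102 CPM), and 7 with the replicate block. Its list had a camera adjusted p of 2.96e-04, with adjusted p = 0.47 with an estimated correlation. Acadm did not pass (log2 fold change 0.76, adjusted p = 0.0621), and passed with the block (adjusted p = 0.011), with no filter or the stricter one, by DESeq2 or limma-voom and without RACM p0 (adjusted p from 0.0115 to 0.0476). In glycolysis 4 of 22 genes rose (8 adjusted over the list alone, and 7 over all genes with the replicate block), at a camera adjusted p of 5.26e-04 and an adjusted p = 0.42 with an estimated correlation. Hk2 had a log2 fold change of 0.94 and Pkm one of 0.79, while 15.3% of the exon bases of Pkm and 19.6% of those of Fabp3 were shared with other genes. Hk2 lost its call without PC p2, PC p4, RACM p0 or RACM p2 (adjusted p from 0.054 to 0.103), and Pkm without PC p0, PC p4, RACM p2 or RACM p4 (adjusted p from 0.0995 to 0.177). Summed oxidative phosphorylation genes were at 29150, 22470 and 29680 CPM in PC p0, p2 and p4, and 22930, 14170 and 15060 CPM in RACM. RACM p0 thus lay above PC p2, as it did for fatty acid oxidation (7408 against 6863 CPM) and glycolysis (7060 against 6156 CPM). Beside these lists, summed fibroblast markers lay between 755 and 1938 CPM in PC libraries and between 1179 and 7581 CPM in RACM libraries.

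Receptor and second-messenger genes changed in both directions. Of 24 genes of autonomic receptors and cAMP signalling, 8 rose and 3 fell (13 adjusted over the list alone), led by regulators of G-protein signalling: Rgs4 rose from 0.975 to 96.9 CPM (log2 fold change 6.58 ± 0.41) and Rgs2 fell from 69.5 to 12.1 CPM (-2.52 ± 0.19). The camera adjusted p was 0.0238, with adjusted p = 0.243 with an estimated correlation, and the call was lost without PC p2 or RACM p0 (adjusted p = 0.0511 and 0.055). In BMP and TGF-beta signalling 6 of 20 rose and 2 fell (12 adjusted over the list alone). The growth factor gene Bmp2 rose by a log2 fold change of 3.37 ± 0.26 (166 CPM in PC), opposite to Bmp10. The camera adjusted p was 0.00191, with adjusted p = 0.357 with an estimated correlation, and it was lost without PC p0 (adjusted p = 0.0688). Wnt signalling had 3 risers among 18 genes (6 adjusted over the list alone; 5 risers and 1 fall with the replicate block), among them the secreted Wnt antagonist Sfrp5 (28.3 against 2.87 CPM) and the ligand Wnt5a (log2 fold change 1.64). That list did not pass (camera adjusted p = 0.0561, median -0.004 and mean 0.25 on the log2 scale), and passed with upper-quartile scaling (adjusted p = 0.0471), with no filter or the stricter one, and without PC p4, RACM p4 (0.0281 and 0.0162) or both p4 libraries, within a range from 0.00624 to 0.57 over its alternatives.

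Of 10 measured Notch signalling genes, 5 fell in PC and none rose (8 adjusted over the list alone). The target gene Hey1 fell from 48.2 to 6.56 CPM (log2 fold change -2.88 ± 0.34) and the ligand gene Jag1 from 27.1 to 7.87 CPM (-1.78 ± 0.25). The camera adjusted p was 1.12e-06, with adjusted p = 0.127 with an estimated correlation. Summed CPM of the Notch list was 123, 112 and 112 in PC p0, p2 and p4, and 216, 279 and 424 in RACM, where summed fibroblast markers were 1179, 2734 and 7581 CPM and macrophage markers 220, 575 and 965 CPM. Jag1 did not rise with these sums, at 27.4, 26.8 and 27.1 CPM in RACM p0, p2 and p4. Hey1 was at 41.6, 40.3 and 62.7 CPM in the same libraries. Notch3, looked up after its values were seen and also on the pericyte list, was at 5.70 ± 0.42 CPM in PC and 38.1 ± 33.0 CPM in RACM. Genes of axon guidance and neural adhesion had 10 of 33 higher and 4 lower (20 adjusted over the list alone). The ephrin gene Efnb2 and the teneurin gene Tenm3 each had a log2 fold change of 3.37, at 103 and 129 CPM in PC. Slit2, a guidance cue, fell from 53.8 to 8.74 CPM. The camera adjusted p was 2.81e-06, with adjusted p = 0.18 with an estimated correlation. The median log2 fold change of this list was 0.09 and its mean 0.65. That median changed sign over the alternatives, from -0.35 to 0.67.

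**Figure D3:**
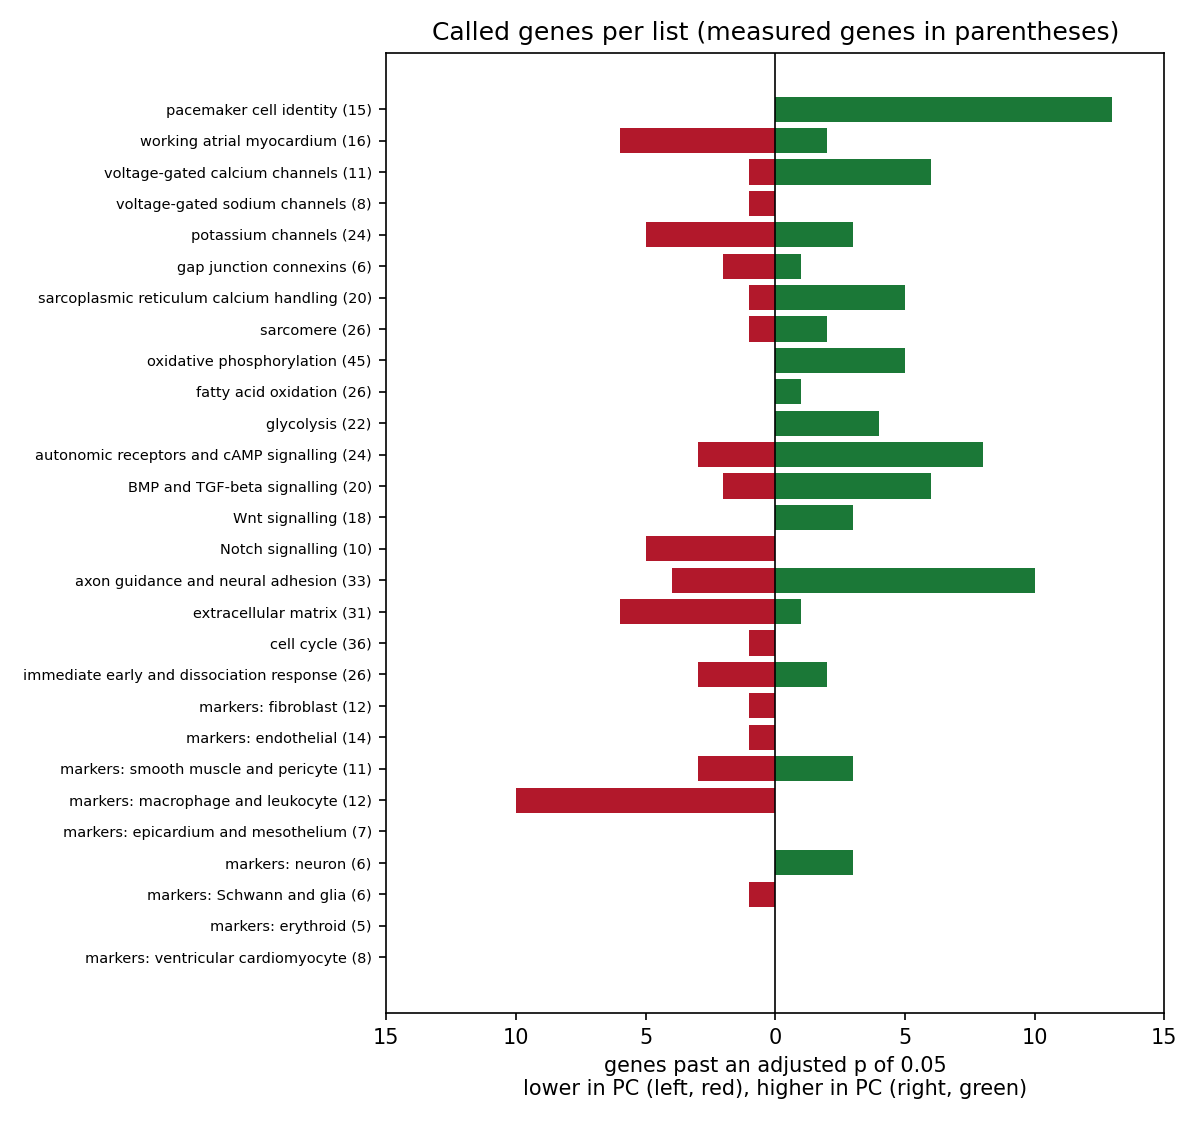
Number of genes past an adjusted p of 0.05 in the fixed lists, with genes higher in PC to the right in green and lower to the left in red, and the number measured after each name. Pacemaker cell identity had 13 of 15 genes higher, and the macrophage markers 10 of 12 lower.

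Markers of other cell types differed between the sorts. Of 12 macrophage and leukocyte markers, 10 fell in PC and none rose (12 adjusted over the list alone), with a median log2 fold change of -3.94. Fcer1g stood at 2.43 ± 0.61 CPM in PC and 36.8 ± 16.6 CPM in RACM, and Tyrobp at 1.63 against 36.2 CPM. The list's camera adjusted p was 2.33e-16, with adjusted p = 0.243 with an estimated correlation. Fibroblast markers had 1 fall among 12 (6 adjusted over the list alone) and 8 with the replicate block, with a camera adjusted p of 5.38e-04 and adjusted p = 0.466 with an estimated correlation. Their summed level in PC p0, p2 and p4 was 755, 901 and 1938 CPM, against 1179, 2734 and 7581 CPM in RACM. Dpt, the fibroblast gene that fell (-2.67), lost its call without PC p0, PC p2, RACM p2 or RACM p4 (adjusted p from 0.06 to 0.135), and Tcf21 (-2.32) did not pass (adjusted p = 0.0514; 0.0472 with the block), but passed with upper-quartile scaling, with no filter or the stricter one, by DESeq2 and without RACM p0 (from 1.01e-05 to 0.0473). Of 31 extracellular matrix genes, 6 of which stand in other lists too, 6 fell and 1, Smoc2, rose (19 adjusted over the list alone), and 18 fell with the replicate block. Fbln1 of the matrix fell from 203 to 78.9 CPM. The matrix list's camera adjusted p was 8.72e-06, with adjusted p = 0.466 with an estimated correlation.

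Endothelial markers had 1 fall among 14 (3 adjusted over the list alone, and 3 with the replicate block), with a camera adjusted p of 0.0292 and adjusted p = 0.466 with an estimated correlation; this list's call was lost without PC p0, PC p2 or RACM p0 (adjusted p = 0.0688, 0.243 and 0.0781). The gene was Tek (-2.14), whose call was lost without PC p0, PC p2, PC p4, RACM p2 or RACM p4 (adjusted p from 0.0597 to 0.143) and by limma-voom (0.0866), and Eng (-1.22) did not pass (adjusted p = 0.0945; 0.0107 with the block), but passed with no filter, by DESeq2, without PC p4 and without both p4 libraries (from 0.00588 to 0.0205). Smooth muscle and pericyte markers split, with 3 of 11 higher, Cnn1 (58.7 against 28.1 CPM), Myh11 (log2 fold change 2.68) and Cspg4 (1.27), and 3 lower, Abcc9, Pdgfrb (-3.14) and Notch3 (-2.74) (9 adjusted over the list alone; 4 higher and 5 lower with the block); the list did not pass (camera adjusted p = 0.499, median 0.11 and mean -0.72). Of these genes, those besides Cnn1 and Abcc9 were chosen after their values were seen. Calls were lost for Myh11 without PC p0 or PC p4 (adjusted p = 0.0648 and 0.0507), for Cspg4 without PC p0, RACM p2 or RACM p4 (from 0.0501 to 0.0786) and for Pdgfrb without PC p0 or RACM p2 (0.0525 and 0.0561). That of Notch3 was lost by limma-voom (0.149) and without any 1 library but RACM p0 (from 0.0849 to 0.124), and all 4 were lost without both p4 libraries (from 0.0569 to 0.129). Rgs5 (-1.98), Kcnj8 (-3.60) and Acta2 (1.48) of that list, also chosen afterwards, did not pass (adjusted p = 0.0749, 0.144 and 0.0909). They passed with the block (0.0321, 0.035 and 0.00991) and with no filter (2.02e-05, 0.00724 and 1.55e-04), and Rgs5 also without RACM p0 (0.0348), Kcnj8 without PC p0 (0.0191), and Acta2 by limma-voom (0.048), without RACM p4 (0.00176) and without both p4 libraries (0.00468). Kcnj8 was at 0.353 ± 0.612 CPM in PC and 4.31 ± 2.26 CPM in RACM. Without PC p0 its log2 fold change went to -9.29, so that pass rests on PC libraries at the floor. None of 7 epicardial markers passed (1 adjusted over the list alone, 2 lower with the block), at a camera adjusted p of 0.0201 that was lost with an estimated correlation (adjusted p = 0.339) and without PC p2 (adjusted p = 0.0511). Aldh1a2 of that list was at 4.25 ± 5.28 against 37.3 ± 43.2 CPM (adjusted p = 0.123; 0.00145 with the block), and passed with no filter, without PC p4 and without both p4 libraries (from 6.73e-05 to 0.0492).

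Of 16 listed neuron markers only 6 passed the filter, and the rest did not enter the list test. Among the 6 measured, 3 rose and none fell (4 adjusted over the list alone), namely Th, Uchl1 (112 ± 20.5 against 5.36 ± 0.64 CPM, with 18.1% of its exon bases shared) and Dbh. Th, with 6 counts over the RACM libraries, passed the filter only through PC. The list had a camera adjusted p of 7.14e-15, adjusted p = 0.0164 with an estimated correlation, and adjusted p = 0.235 with that and the replicate block. These values cover the measured genes and not neuron markers as a set. Of 6 Schwann and glial markers 1 fell, Mbp (50.4 to 11.5 CPM; 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0686), although it did without PC p2, PC p4, RACM p0, RACM p4 or both p4 libraries, with no filter or the stricter one, and by fry (adjusted p from 0.00788 to 0.0443). No erythroid marker of 5 and no ventricular marker of 8 passed (0 adjusted over either list alone), and neither list passed (camera adjusted p = 0.132 and 0.154). The erythroid list passed with the replicate block (adjusted p = 0.0163) and without PC p0 or RACM p2 (0.0105 and 0.0175), and the ventricular list without RACM p4 (0.039) or both p4 libraries (0.0284). The ventricular light chain gene Myl3 was at 164 against 290 CPM (adjusted p = 0.111; 0.0428 with the block), and passed with no filter, by DESeq2, without PC p4 and without both p4 libraries (from 0.012 to 0.0413).

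Of 36 cell cycle genes 1 fell, Mybl2, at 0.933 against 4.61 CPM (0 adjusted over the list alone), a call lost without any 1 library but RACM p0 (adjusted p from 0.0755 to 0.192) and by limma-voom (0.0724). The list lay lower by camera (adjusted p = 0.0309), with adjusted p = 0.67 with an estimated correlation, a call lost without PC p0 or PC p2 (adjusted p = 0.184 and 0.416) and turned without RACM p4 (adjusted p = 0.949). Of 26 immediate early and dissociation response genes, 2 rose and 3 fell (7 adjusted over the list alone), with Socs3 at 105 against 39.6 CPM and Myc with a log2 fold change of -2.17, a call lost without both p4 libraries (adjusted p = 0.054). That list did not pass (camera adjusted p = 0.139), and passed without RACM p0 (adjusted p = 0.00765). Summed macrophage markers were 35.3, 13.4 and 62.2 CPM in PC p0, p2 and p4, and 220, 575 and 965 CPM in RACM. The mitochondrially encoded genes had 0 counts in every library, so their list was not tested.

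**Figure D4:**
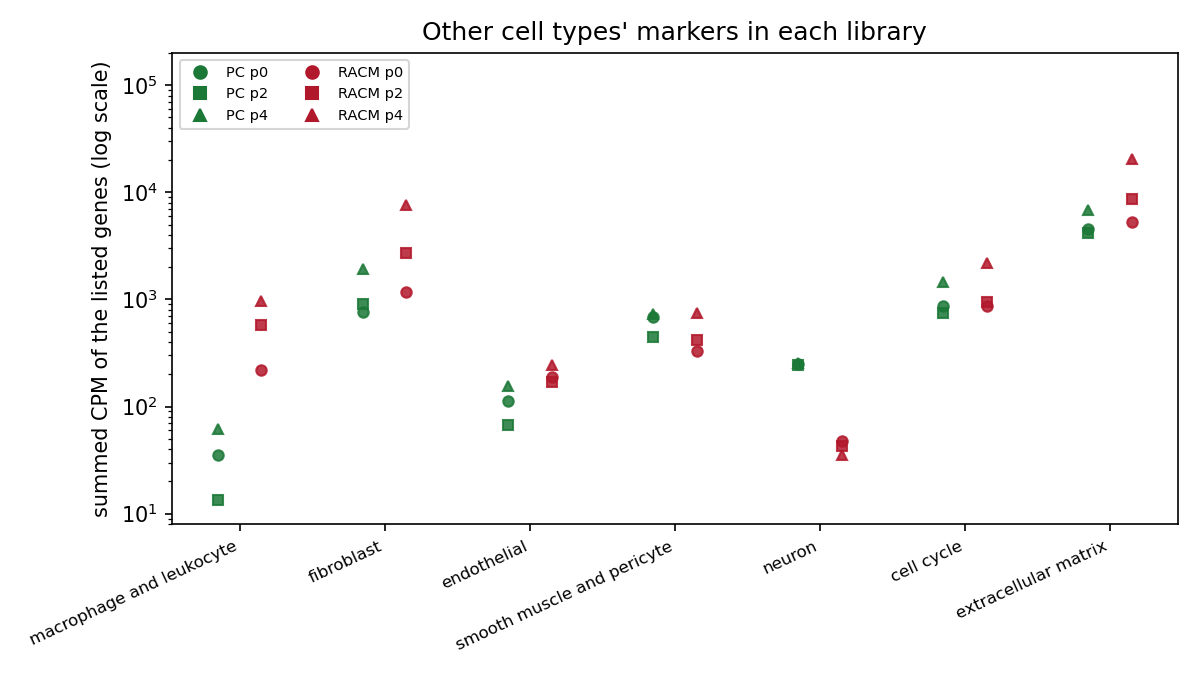
Summed CPM of the genes of 7 lists in each library, on a log axis. Shape gives the p number, green PC and red RACM. Macrophage markers lay between 13.4 and 62.2 CPM in PC and between 220 and 965 CPM in RACM, and the p4 libraries had the highest fibroblast and cell cycle sums of their cell type.

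The libraries numbered p0, p2 and p4 were also compared across both cell types, with 2 libraries at each number. The labels do not say whether PC and RACM of 1 number came from the same pool of hearts. If they did, the 2 libraries are not independent, and the test cannot tell the number from a difference between pools. Hif3a, an oxygen-regulated transcription factor, was the 1 gene past the test (edgeR quasi-likelihood F test in a model with cell type, adjusted p = 0.0327). It stood at 174, 66.4 and 25.8 CPM in PC p0, p2 and p4, and at 159, 59.9 and 16.6 CPM in RACM. At an unadjusted p below 0.05 there were 2141 genes, where chance gives 901, and 660 genes passed by the DESeq2 likelihood-ratio test. On simulated data the edgeR test of the p number called 24 unchanged genes beside 65% of 200 changed ones. The likelihood-ratio test was not simulated. The next named genes in order of p, Cxcl10, Ube2c, Mhrt, Nppb and Arhgap11a, did not pass here or with RLE scaling (adjusted p from 0.0518 to 0.0744). They passed with no filter (from 3.74e-09 to 9.08e-07), by DESeq2 (from 6.74e-20 to 2.47e-11), without the p2 libraries (from 4.01e-04 to 0.0207) and when adjusted over genes of at least 10 CPM (0.0273 to 0.0391). Cxcl10, a chemokine gene, was at 1.95, 5.66 and 18.5 CPM in PC and 9.46, 30.1 and 72.0 CPM in RACM (adjusted p = 0.0529). The mitotic gene Ube2c was at 55.1 CPM in PC p4 and 62.1 CPM in RACM p4, and between 11.6 and 17.3 CPM in the other libraries. Arhgap11a was at 39.8 and 63.5 CPM in the p4 libraries. Nppb, the gene of B-type natriuretic peptide, was at 23.9, 1.24 and 2.79 CPM in PC and 235, 34.3 and 74.2 CPM in RACM. Mhrt, which shares 39.9% of its exon bases with another gene, was at 44.1, 248 and 142 CPM in PC. The count of calls was 43, 296 and 188 without the p0, p2 and p4 libraries. Such fits have few libraries for their coefficients, so their p-values rest largely on spread pooled over genes. Among sex-linked genes, looked up after their values were seen, the Y-linked Kdm5d was at 8.57, 40.2 and 21.0 CPM in PC p0, p2 and p4 and 9.72, 44.8 and 37.1 CPM in RACM (adjusted p = 0.0881). The Y-linked Ddx3y was at 24.1, 38.1 and 22.6 CPM in PC and 18.4, 52.4 and 47.6 CPM in RACM, and Xist at 930, 710 and 870 CPM in PC and 1147, 230 and 586 CPM in RACM.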

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

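Fits without both p4 libraries, without genes overlapping on the opposite strand, with the replicate block and an estimated correlation together, and with adjustment over genes of at least 10 CPM were chosen after seeing the data. The count of 1309 genes stayed within 1.5 times under RLE (1296) and upper-quartile scaling (1289), the stricter filter (1173), limma-voom (1068), a 2-fold minimum (1088) and without overlapping genes (974). It rose to 2339 with no filter, 2082 with the replicate block and 2362 with DESeq2, was 734 without both p4 libraries, and ranged from 511 to 1338 with each library left out. Fewer libraries enter the fits with libraries left out, and otherwise the cause was not tested. DESeq2 also called more unchanged genes on simulated data, 54 against 6. With no filter, the log2 fold change of Rgs5 went from -1.978 to -1.979, and that of Notch3 from -2.741 to -2.745. Their edgeR adjusted p meanwhile fell from 0.0749 to 2.02e-05 and from 0.0346 to 1.00e-06. That fit was not simulated, so a pass with no filter alone is not stronger evidence for a gene. The count of 19 lists fell to 2 with an estimated correlation, 9 by fry and 0 with the replicate block and an estimated correlation, and ranged from 15 to 21 with each library left out. Fry asks another question than camera, and for the others the cause was not tested. The count of 1 gene for the p number became 720 with no filter, 660 by DESeq2 and 41 over genes of at least 10 CPM, and ranged from 43 to 296 with each number left out; fewer genes were adjusted over in the third, and the cause of the others was not tested.

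The log2 fold change of Myh6, which never passed, turned to -0.018 under upper-quartile scaling and -0.12 without both p4 libraries, with a range from -0.166 to 0.237 over single libraries left out. The sodium channel list, also never called, turned in camera's direction, with medians of -0.312 with no filter and 0.969 without both p4 libraries, and from -0.333 to 0.898 over libraries left out. The cell cycle list turned without RACM p4 (medians from -1.192 to 0.158). The immediate early list turned without both p4 libraries in camera's direction only. Its median stayed negative there (-0.035), as it did over libraries left out (from -0.36 to -0.029). The cause was not tested. Of 85 named genes 71 were called, and 52 of these kept the call without each single library. Without both p4 libraries the calls of C1qa, Cd300ld, Gjd3, Hk2, Mybl2, Myc, Pkm, Scn10a, Sdhd, Tek and Tnf were lost (adjusted p from 0.0517 to 0.215). The replicate block ended no call of a named gene. It added those of Acadm, Aldh1a2, Eng, Myl3 and Tcf21, and of the lists it changed the erythroid markers. For p number genes, fits without p0 or p4 have no p4 minus p0 value. Exon usage was not run. In simulated data with 50 genes changed at each size, 12% of the 2-fold changes were recovered. The real comparison called 1309 genes, and the adjusted threshold is less strict where more genes change. The recovered share therefore may not carry over to the real comparison.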

Other observations

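Some genes outside the named ones were looked up after their values were seen. The teneurin gene Tenm4 was at 421 against 6.73 CPM in PC and RACM, and the nicotinic receptor subunit gene Chrnb4 at 65.0 against 2.81 CPM. The glucagon receptor gene Gcgr was at 79.3 against 2.27 CPM (log2 fold change 5.12) and the PACAP receptor gene Adcyap1r1 at 56.8 against 2.61 CPM (4.41), while the neuropeptide receptor gene Npy1r went the other way, at 6.60 against 41.0 CPM (-2.63). These are single genes, and no theme was tested over them.

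All tests of explanations below were chosen after the result was seen, except the counts over other splits. Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many genes, 1309 against at most 1 in another. For lists the real split gave 19 and the highest other 17, also 1 of 10, that of PC p0 with RACM p2 and RACM p4. Both maxima stand among the splits that part all 3 pairs, and with the replicate block the other splits of this kind called 0 genes against 2082. With 10 splits the share cannot fall below 0.1. Every other split mixes both cell types in each group. Part of the cell type difference then stays between the groups and part enters their spread. The low gene counts and the many lists called in these splits therefore cannot decide on chance. That most list calls were lost with an estimated correlation remains a limit of the calls at the preset one.

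Macrophage genes were lower in PC. A lower share of cardiomyocytes in RACM as the whole reason would raise all other types alike. The log2 ratio of PC to RACM sums was -2.64, -5.42 and -3.96 for macrophage markers at p0, p2 and p4. The highest of these lay 0.67 below the lowest fibroblast or endothelial ratio, which is all the comparison covered. Smooth muscle and pericyte ratios were 1.07, 0.09 and -0.03. Epicardial sums were 18.6, 12.7 and 28.9 CPM in PC and 28.5, 67.9 and 180 CPM in RACM. Erythroid sums were 64.9, 0.395 and 19.0 CPM in PC and 97.9, 13.2 and 67.1 CPM in RACM. Some of these falls lay within the macrophage range. Where the macrophage transcripts in RACM come from stays open and was not tested. Sorted macrophages, carried-over RNA and a difference in macrophages around the muscle cells would all lower these genes in PC. A gate on Myh6-mCherry is meant to exclude macrophages themselves, but the purity of the sort was not measured here. Fibroblast markers, which such a gate should also exclude, summed to 7581 CPM in RACM p4.

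Th, Uchl1 and Calca (61.4 against 1.36 CPM) were higher in PC. Neurons in the sort would bring their other abundant transcripts, but Stmn2, Prph, Snap25, Gap43, Tubb3 and Phox2a together reached at most 5.45% of the CPM of Th in a PC library. These genes come from the neuron list and were chosen after the data were seen. Only Tubb3 among them had passed the filter, so their low sum could have been foreseen. Reads of overlapping genes are argued against for Th and Calca, which share 0% of their exon bases with another gene. For Uchl1, with 18.1% shared, they stay open, since the share of bases does not bound the share of reads. Expression by pacemaker cells themselves was not tested and stays open.

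Fibroblast, matrix and cell cycle genes were highest in the p4 libraries of each cell type. One fibroblast source for the matrix genes would add them in 1 ratio, and over the p0 library the matrix CPM added per fibroblast CPM added, leaving out shared genes, was 1.07 in PC p4, 1.30 in RACM p2 and 1.56 in RACM p4, a spread of 1.46 times. In PC p2, however, fibroblast markers were 146 CPM above PC p0 while matrix genes changed by -525.5 CPM and cell cycle genes by -128.9 CPM, so the ratios of the other libraries do not settle the matter. Cell cycle CPM added per fibroblast CPM added was 0.503, 0.0482 and 0.204 in PC p4, RACM p2 and RACM p4, a spread of 10.4 times that came to 2.47 times without RACM p2. Whether 1 fibroblast source accounts for either group stays open, with 1 library for each number and cell type, as does what the p number stands for.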
